A study of Mus musculus with 15 samples.

How the data were processed

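RNA-seq of 15 mouse libraries in 5 groups of 3 was used: sorted decidual endothelial cells, the bEnd5 endothelioma line, mural trophectoderm at E4.5 and at E4.75, and trophoblast giant cells (TGC) grown from E4.5 mural trophectoderm. Per the labels' protocols, the 2 endothelial groups were made from purified RNA (10 ng) and the 3 trophoblast groups from cell lysate (3 µl), all with a low-input kit that amplifies cDNA. E4.5 mural trophectoderm, TGC and decidua were of the strain B6C3F1, and E4.75 embryos were CD1, per the labels. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, nominally scaled to the depth of the library) for 36052 genes, with 1 column per library. Per the submitters' processing notes, TopHat, HTSeq 0.11.2 and DESeq2 were used with the mouse build mm10 (GRCm38); which of them made the FPKM values, the annotation and the strand setting of the counting are not given in the sources used here. Columns were matched to samples by their titles, and groups and replicate numbers come from the labels.

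In a table of FPKM from whole reads, each gene's values are multiples of what 1 read is worth in each library, and these steps were recovered for every library and gene. All values came out whole (100% of values, tolerance 0.001 reads). Reads on genes ranged from 4.32 to 22.5 M per library, and the scaling factors of the libraries differed by up to 3.31 times. On simulated tables of 3000 genes, the step was recovered in 99.9% of genes, and in 100% up to a common divisor. Counting floors and read numbers cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Pairs of replicates in 1 group differed by more than sampling noise (chi-square per degree of freedom 6.09 to 151), so none was taken for a copy of another, which does not show that they came from separate animals. Gene coordinates and exon lengths are from the GENCODE M21 annotation of GRCm38, matched by symbol for 33459 genes (92.8%). The recovered step matched the exon length within 10% for 74.6% of the matched genes.

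Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), 1 mean per group, with Benjamini-Hochberg adjustment over the genes tested and calls at an adjusted p below 0.05. Fold changes are on that log2 scale with the pseudocount of 1, which understates the change of genes at low levels. Genes with an FPKM of 1 or more in at least 3 libraries of the fit were kept. bEnd5 against decidual endothelium was fitted on the 6 endothelial libraries, the 3 trophoblast comparisons on the 9 trophoblast libraries, and TGC against decidual endothelium on all 15. The spread between libraries is thus shared within a fit. The authors' scaling of FPKM was kept. With it the FPKM totals of the libraries differed, from 1.8e+05 in bEnd5 replicate 2 to 1.01e+06 in TGC replicate 3. TGC replicates 1 and 2 had totals of 4.22e+05 and 4.75e+05. Levels of different groups are thus not on the same total. The 43 gene lists, the design, the alternatives and the rule for named genes were set before the data were examined.

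Lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Shares of a list are of its members that passed the filter. Each list's called members were counted over all genes tested and adjusted over the list alone. Named genes were the 6 highest and 6 lowest called genes of a comparison with a mean of 10 FPKM or more in the higher group and no overlap between the groups, leaving out predicted, mitochondrial, small RNA and pseudogene names. They also were up to 3 called members of a list in its main direction and up to 2 in the other, a fixed set of marker genes, and for TGC against decidual endothelium the members of the ligand and receptor lists. Any 1 gene's groups fail to overlap by chance in 10% of cases with 3 libraries against 3. The identity genes Krt8, Prss29, Spink3, Hba-a1 and Eif2s3y of the description of the libraries were chosen after their values were seen, as were the genes in the plots. Fold changes that share the E4.5 libraries were set beside 100 draws of unchanged groups against the same controls, made from the residuals of the libraries. These draws were first made by flipping signs of residuals and then replaced by random normal combinations, with the same outcome.

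Alternatives were pseudocounts of 0.1 and 5, no filter, a filter on the mean, 3 other scalings (each library at the same total, quantile normalization, median-of-ratios size factors), all 15 libraries in 1 fit or only the 6 compared, the replicate number as a block, eBayes without trend and robust, array weights, and each library left out in turn. After the data were seen, 4 alternatives were added: voom on the recovered reads, the mean FPKM of 1242 olfactory receptor genes subtracted from each library, and each library's trend of log2 values on exon length removed (lowess, span 0.3), among all genes with a length or only among genes at a mean of 5 FPKM or more. For the correlation of fold changes, the 3 other scalings were added later as well. The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold per comparison. These genes were drawn from those at a mean of 10 FPKM or more in the group compared against. At 4-fold they recovered 73% of the changed genes in the fit of bEnd5 against decidual endothelium, 59% in that of E4.75 against E4.5, 51% and 49% in those of TGC against E4.5 and E4.75, and 69% in that of TGC against decidual endothelium; at 2-fold these shares were 37%, 3%, 5%, 10% and 24%. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.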

Results

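RNA was sequenced from maternal and embryonic mouse cells of the time of implantation and from an endothelial cell line, in 5 groups with 3 libraries each. On the maternal side were endothelial cells of the decidua at embryonic day 5.5 (E5.5), sorted as CD31-positive and CD45-negative cells. Beside them stood bEnd5, a mouse brain endothelioma line that carried tdTomato and was grown for 3 days in IVC2, an embryo culture medium. On the embryonic side was mural trophectoderm, the part of the blastocyst wall away from the inner cell mass, laser-dissected at E4.5 and at E4.75. Trophoblast giant cells (TGC) were obtained by growing E4.5 mural trophectoderm for 3 days in IVC2. Whole reads on genes, recovered from the deposited FPKM values, averaged 10.9 ± 1.73 M (SD, n = 3) in decidual endothelium and 7.06 ± 0.84 M in bEnd5. They averaged 14.3 ± 0.66 M at E4.5, 20.6 ± 3.14 M at E4.75 and 7.47 ± 2.78 M in TGC. The shallowest library was TGC replicate 2 with 4.32 M. It had 21196 genes at an FPKM of 1 or more, against 12239 and 12441 in TGC replicates 1 and 3. Pearson's r of log2 values between TGC replicates was 0.836 to 0.907, against 0.959 to 0.989 within the other groups. Mitochondrially encoded genes took 7.03%, 11.1% and 22.2% of the reads of the 3 TGC libraries, against 1.86 ± 0.67% (SD, n = 3) in decidual endothelium. The labels do not say that the libraries of a group came from separate animals or cultures. The p-values of limma thus measure only the spread between these samples, which may be technical. Those of camera at its preset correlation set a list's members against the other genes. They treat genes as nearly independent and take little account of that spread.

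The identity genes followed the labels, except that Prl3d1 also had reads in both endothelial groups and Cdh5 and Pecam1 were also present in TGC. Cdh5 was at 69.8, 14.2 and 194 FPKM in TGC replicates 1, 2 and 3, against a mean of 147 in decidual endothelium. The TGC mean of Pecam1 was 40.7% of that in decidual endothelium. The sort gene Pecam1 (CD31) reached 137 ± 7.75 FPKM (SD, n = 3) in decidual endothelium and 147 ± 22.2 in bEnd5, while Ptprc (CD45) had 2 reads over the 3 libraries of the sorted cells. The keratin gene Krt8 was at 2975 ± 376 FPKM in E4.5, 3916 ± 2099 in E4.75 and 2122 ± 1562 in TGC libraries, and at 0.888 ± 0.589 in decidual endothelium. Prl3d1, the placental lactogen gene of giant cells, was at 0.195 ± 0.169 FPKM in E4.5, 60.8 ± 83.6 in E4.75 and 15681 ± 18312 in TGC libraries. In decidual endothelium it was at 3.74 ± 5.07 FPKM, a mean above that of E4.5. The Y-linked gene Eif2s3y had 0 reads in the 3 decidual libraries, where a count of 0 allows up to 3 reads per library (counting error only), and 17.5 ± 8.63 FPKM at E4.5. Genes of other uterine cells were present in the sorted endothelium. Prss29, a serine protease gene of uterine glands, was at 324 ± 178 FPKM there, the epithelial gene Spink3 at 50.1 ± 43.7 and the globin gene Hba-a1 at 21.1 ± 14.3.

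**Figure D1:**
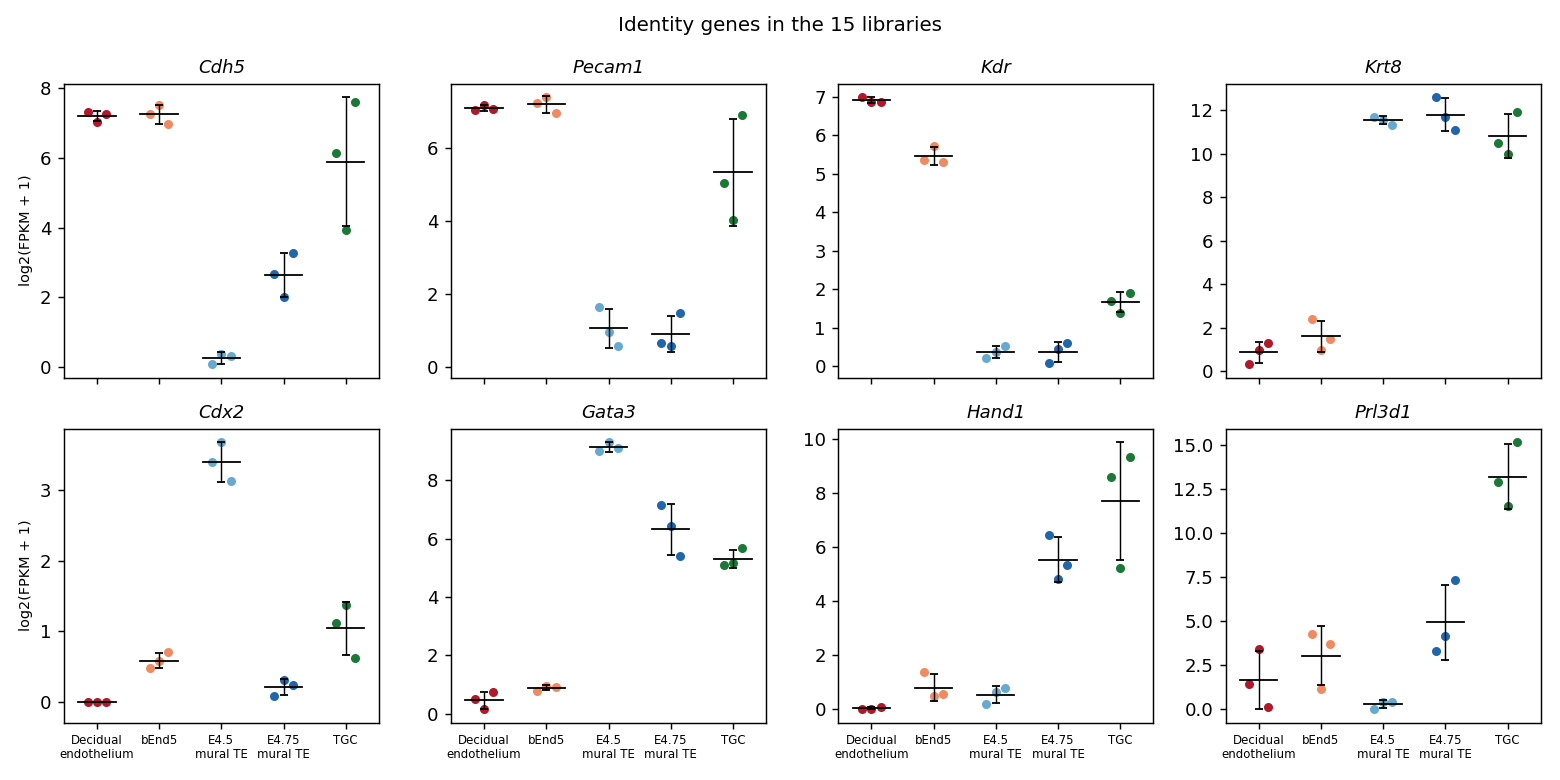
Log2(FPKM + 1) of 8 identity genes in each of the 15 libraries (3 points per group), with the group mean (line) and SD (bar, n = 3). Cdh5 and Pecam1 had similar means in both endothelial groups, lower ones in TGC and the lowest in both mural trophectoderm groups. Cdh5 was not called between TGC and decidual endothelium. Hand1 and Prl3d1 had higher means at E4.75 than at E4.5 and the highest in TGC, where Hand1 was not called against E4.75.

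bEnd5 cells were set against decidual endothelium, which asks how far the cultured line resembles the vessels that the embryo meets. Rbp7, a retinol-binding protein gene (GRCm38 chromosome 4, 149449687 to 149454978), fell from 1059 ± 148 to 0.414 ± 0.0874 FPKM (SD, n = 3). Rgcc (chromosome 14, 79288756 to 79301645) fell from 655 ± 146 to 0.446 ± 0.206, and Aplnr, the apelin receptor gene, from 266 ± 30.1 to 0.363 ± 0.0120. Higher in bEnd5 were the homeobox gene Rhox5 (chromosome X, 37804842 to 37808876), at 165 ± 30.0 against 0.403 ± 0.618 FPKM, and the neuronal pentraxin gene Nptx1 (chromosome 11, 119538719 to 119547753), at 114 ± 14.4 against 0.0632 ± 0.0693. The log2 fold changes were -9.54 ± 0.16 for Rbp7, -8.81 ± 0.21 for Rgcc and -7.61 ± 0.14 for Aplnr (SE). They were 6.95 ± 0.30 for Rhox5, 6.75 ± 0.15 for Nptx1, 5.84 ± 0.43 for the chemokine gene Ccl2 and 5.59 ± 0.19 for the chromatin gene Hmga2. The limma adjusted p of these genes was at most 2.25e-05. Sparcl1, Prss29 and the caveolar gene Sdpr completed the lowest 6 (-7.84, -7.77 and -6.50), and the hyaluronan receptor gene Lyve1 and S100a4 the highest 6 (5.29 and 5.29).

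The pan-endothelial genes Cdh5 (VE-cadherin) and Pecam1 were not called between the endothelial groups. Their log2 fold changes were 0.05 ± 0.20 (SE, adjusted p = 0.817) and 0.09 ± 0.18 (adjusted p = 0.662). Both were called higher in bEnd5 with each library brought to the same total (0.60 and 0.63), with median-of-ratios size factors (0.48 and 0.52) and with quantile normalization (1.21 and 1.24). Of the pan-endothelial list, 3 of 26 tested members rose, 18 fell and 5 did not pass the test (3 and 19 adjusted over the list alone). The tight-junction gene Cldn5 (-4.91) and Sox17 (-3.95) were among those lower, and the transcription factor gene Erg (1.32) among those higher; camera did not call the list (adjusted p = 0.134). Among arterial endothelial genes, 1 of 14 tested members rose, 13 fell and 0 did not pass the test (1 and 13 adjusted over the list alone). The connexin gene Gja4 (-5.22 ± 0.17), the Notch target Hey1 (-3.87 ± 0.20) and Gja5 (-3.58 ± 0.17) were lower and Notch4 (0.83 ± 0.21) higher. The arterial list had a median log2 fold change of -2.43 and a camera adjusted p of 0.00589 (adjusted p = 0.724 with an estimated correlation). That call was lost without decidual replicate 1 (median -2.15, adjusted p = 0.0830) or decidual replicate 3 (median -2.21, adjusted p = 0.0591).

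Nuclear-encoded respiratory chain genes were lower in the line, where 0 of 27 tested members rose, 25 fell and 2 did not pass the test (0 and 25 adjusted over the list alone). Ndufa2 (-4.10 ± 0.25) and Ndufa4 (-3.75 ± 0.30) were examples. The respiratory chain list had a median log2 fold change of -2.41 and a camera adjusted p of 1.65e-04 (adjusted p = 0.756 with an estimated correlation). Of class I antigen presentation genes, 11 of 11 tested members fell and none rose (11 adjusted over the list alone). They included the immunoproteasome gene Psmb8 (-4.56 ± 0.18) and the peptide transporter gene Tap2 (-2.56 ± 0.20). The antigen presentation list had a median log2 fold change of -2.30 and a camera adjusted p of 0.010 (adjusted p = 0.724 with an estimated correlation). For ribosomal protein genes, 1 of 26 tested members rose, 19 fell and 6 did not pass the test (1 and 19 adjusted over the list alone). The ribosomal protein list had a median log2 fold change of -1.34 and a camera adjusted p of 0.0241 (adjusted p = 0.761 with an estimated correlation). That call was lost with quantile normalization (median -0.20, adjusted p = 0.474). At a median much as before, it was lost with the background of olfactory receptor genes subtracted (-1.35, adjusted p = 0.0853), and without bEnd5 replicate 1 (median -1.36, adjusted p = 0.0637), bEnd5 replicate 2 (median -1.33, adjusted p = 0.0551) or bEnd5 replicate 3 (median -1.40, adjusted p = 0.0652). Short transcripts were lower in bEnd5 as a class. Among genes at a mean of 5 FPKM or more, the median log2 fold change was -2.15 for 289 genes with up to 1000 bp of exon and -0.21 for 3158 genes with over 4000 bp. With that trend removed, the ribosomal protein median was 0.16 (camera adjusted p = 0.946) and the respiratory chain median -1.35 (adjusted p = 0.00295). The removal of the trend and the subtraction of the background were alternatives chosen after the data were seen.

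Of mesenchymal and motility genes, 8 of 18 rose and 4 fell (8 and 5 adjusted over the list alone). The fibronectin gene Fn1 (3.66 ± 0.17) and Cd44 (3.16 ± 0.13) were higher. Camera gave that list an adjusted p of 0.134, and 0.0466 with quantile normalization. Of signalling genes, Apln, the ligand of Aplnr, was higher in the line (3.38 ± 0.17), as were Sema3a (4.92 ± 0.13) and the integrin gene Itgb3 (1.96 ± 0.17). Pdgfb (-2.74 ± 0.17), Dll4 (-2.27 ± 0.31) and Kdr, the VEGF receptor 2 gene (-1.45 ± 0.17), were lower. Kdr was not called with quantile normalization (-0.39, adjusted p = 0.0769). Uterine epithelial genes were lower in the line in 3 of 4 cases and higher in 1 (3 and 1 adjusted over the list alone), including Clu (-5.45). Erythroid and platelet genes were lower in 4 of 6 and higher in 1 (4 and 1 adjusted over the list alone), including Hba-a1 (-3.93).

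Of 11881 genes tested, limma called 8077, with 2988 higher and 5089 lower in bEnd5 (37.0% higher, median log2 fold change over all tested genes -0.29). The split turned with the scaling. With each library brought to the same total it was 4427 higher and 3537 lower (55.6% higher, median 0.17), and with quantile normalization 4432 and 3817 (53.7%, median 0.07). With median-of-ratios size factors it was 4242 and 3891 (52.2%, median 0.04). Without the filter on low values 22712 genes were called, 17469 of them higher. Olfactory receptor genes averaged 0.388 ± 0.054 FPKM (SD, n = 3) in bEnd5 against 0.00451 ± 0.00125 in decidual endothelium. Leaving out bEnd5 replicate 1, 2 or 3, where the filter removes genes present in bEnd5 alone, left 1480, 1577 or 1696 genes higher.

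At E4.75, mural trophectoderm was set against E4.5, which spans the time around attachment. Hand1, a transcription factor gene required for giant cells (chromosome 11, 57828705 to 57832818), was at 50.7 ± 31.3 against 0.455 ± 0.303 FPKM (SD, n = 3), a log2 fold change of 5.01 ± 0.87 (SE). Prl3d1 (chromosome 13, 27094190 to 27100258) rose by 4.66 ± 1.03 on the log2 scale, a call that ended with a pseudocount of 5 (adjusted p = 0.0650). The trophectoderm regulators Cdx2 (-3.20 ± 0.28) and Gata3 (-2.82 ± 0.41), the pluripotency gene Nanog (-3.06 ± 0.30) and the endocytic adaptor gene Dab2 (-4.56 ± 0.73) were lower. Of the trophectoderm list, 3 of 20 tested members rose, 7 fell and 10 did not pass the test (3 and 8 adjusted over the list alone), and camera did not call it (adjusted p = 0.323). Pluripotency genes rose in 1 of 10 cases and fell in 1 (1 and 1 adjusted over the list alone; camera adjusted p = 0.710). The kallikrein gene Klk7 (chromosome 7, 43811294 to 43816359) rose most, to 267 ± 78.0 from 0.991 ± 1.27 FPKM (7.23 ± 0.59). The death ligand gene Fasl (6.33 ± 0.53), Tpm3-rs7 (5.97), the myosin light chain gene Myl9 (5.92 ± 0.52), Fos (5.84 ± 0.66) and the natriuretic peptide gene Nppb (5.68 ± 0.62) completed the highest 6. The lowest 6 were Rps3a3 (-7.88), Trim43a (-7.43 ± 0.34), Pramel6 (-6.49 ± 0.57), Rps3a2 (-5.72), Arhgap8 (-5.57 ± 0.42) and Pramel7 (-5.56 ± 0.71). The adjusted p of these genes was at most 0.00874. Rps3a2, Rps3a3, Tpm3-rs7, Trim43a, Prl3d1 and the Pramel genes have near-identical copies, so their reads could have been split among relatives.

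In the giant cell list, 6 of 25 tested members rose, 1 fell and 18 did not pass the test (7 and 1 adjusted over the list alone). Camera did not call it (adjusted p = 0.0550), but did with a pseudocount of 0.1 (0.0188), at the same total (0.0428) and with the background subtracted (0.0463). Of immediate early genes, 6 of 18 tested members rose, 0 fell and 12 did not pass the test (6 and 0 adjusted over the list alone), led by Fos, Fosb (3.85 ± 0.57) and Klf4 (2.22 ± 0.32). The immediate early list had a median log2 fold change of 1.05 and a camera adjusted p of 0.00492 (adjusted p = 0.894 with an estimated correlation). In the integrin list, 6 of 10 tested members rose, 1 fell and 3 did not pass the test (6 and 1 adjusted over the list alone). Itgb3, which encodes the beta subunit of the vitronectin receptor (4.12 ± 0.39), and Itga7 (3.26 ± 0.52) were higher. Camera gave that list an adjusted p of 0.0514, and called it with a pseudocount of 0.1 (0.0326), at the same total (0.0300) and with the background subtracted (0.0463). Glycolytic and hypoxia genes rose in 4 of 22 cases and fell in 1 (4 and 2 adjusted over the list alone). The glucose transporter gene Slc2a1 rose from 23.8 ± 22.7 to 305 ± 106 FPKM (3.96 ± 0.67), Ankrd37 was higher (3.20 ± 0.34) and Ndrg1 lower (-2.57 ± 0.36). Targets of p53 fell in 5 of 16 cases and rose in 0 (6 and 0 adjusted over the list alone), including the cell cycle inhibitor gene Cdkn1a (-3.29 ± 0.59) and Mdm2 (-3.12 ± 0.29). Camera gave them an adjusted p of 0.0832, and 0.0300 with each library at the same total. The inhibitor gene Cdkn1c was higher (3.05 ± 0.50).

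Ribosomal protein genes fell at E4.75 in 7 of 26 cases and rose in none (8 adjusted over the list alone). The ribosomal protein list had a median log2 fold change of -0.64 and a camera adjusted p of 0.00492 (adjusted p = 0.894 with an estimated correlation). Quantile normalization ended that call (median -0.17, adjusted p = 0.320), as did removing the length trend among genes at a mean of 5 FPKM or more (-0.42, adjusted p = 0.0568) and leaving out E4.5 replicate 1 (median -0.47, adjusted p = 0.0535). Pdgfa, a growth factor gene, rose from 84.4 ± 23.5 to 223 ± 51.6 FPKM (1.41 ± 0.35, adjusted p = 0.0168). It was not called without E4.5 replicate 1 (1.15, adjusted p = 0.0681) or E4.75 replicate 2 (1.24, adjusted p = 0.0774). The tissue plasminogen activator gene Plat fell (-5.12 ± 0.54). Of 13368 genes tested, 3090 were called, with 1233 higher and 1857 lower at E4.75 (39.9% higher, median -0.08). The split was 1355 and 863 (61.1% higher, median 0.18) with each library brought to the same total. The strain went with the stage, since E4.75 embryos were CD1 and E4.5 embryos B6C3F1. The count was 1723 without E4.5 replicate 2, 2002 without E4.5 replicate 3, 1948 without E4.75 replicate 2 and 1830 without E4.75 replicate 3. With array weights, whose estimation stopped short of convergence, it was 6598, and with no filter 1931. Genes called higher numbered 645 and 757 without E4.5 replicates 2 and 3, and 713, 729 and 735 without E4.75 replicates 1, 2 and 3. Those called lower numbered 1078 without E4.5 replicate 2 and 1219 and 1095 without E4.75 replicates 2 and 3.

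TGC were then set against the E4.5 mural trophectoderm from which they were grown. Prl3d1 rose most. It was at 15681 ± 18312 FPKM (SD, n = 3), a log2 fold change of 12.93 ± 1.03 (SE). Prl7a1 (chromosome 13, 27633366 to 27642493) was at 7123 ± 7887 (11.69 ± 1.40) and Prl3d2 at 5328 ± 5822 (11.31 ± 0.96). Prl3d3, Ceacam15 and Plac8 completed the highest 6 (10.63, 9.78 and 9.26), and Hand1 rose by 7.18 ± 0.87 on the log2 scale. The alcohol dehydrogenase gene Adh1 (chromosome 3, 138260991 to 138290698) had 8927 ± 1955 FPKM at E4.5 and 1.79 ± 1.85 in TGC (-11.84 ± 0.67). The tetraspanin gene Tspan8 (-10.20 ± 0.49), Calcoco2 (-10.09), Prps1 (-9.82), Dppa1 (-9.27) and Dppa5a (-8.96 ± 0.58) fell with it. The adjusted p of the genes in this paragraph was at most 9.43e-05. The Prl and Ceacam genes form families with similar sequences, so the share of each member is uncertain.

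In the giant cell list, 19 of 25 tested members rose, 2 fell and 4 did not pass the test (19 and 2 adjusted over the list alone). The giant cell list had a median log2 fold change of 5.23 and a camera adjusted p of 1.51e-08 (adjusted p = 0.520 with an estimated correlation). In the trophectoderm list, 2 of 20 tested members rose, 12 fell and 6 did not pass the test (2 and 12 adjusted over the list alone). Id2 (-7.27 ± 0.80), the water channel gene Aqp3 (-6.61 ± 0.36), Gata3 (-3.83 ± 0.41) and Cdx2 (-2.37 ± 0.28) were lower and Krt19 (3.15 ± 0.46) higher. The trophectoderm list had a median log2 fold change of -1.82 and a camera adjusted p of 0.0230 (adjusted p = 0.537 with an estimated correlation). That call was lost with quantile normalization (median -1.29, adjusted p = 0.130), and without E4.5 replicate 2 (median -1.52, adjusted p = 0.0526) or TGC replicate 2 (median -1.47, adjusted p = 0.144). Of DNA replication genes, 2 of 29 tested members rose, 17 fell and 10 did not pass the test (2 and 17 adjusted over the list alone). The licensing gene Mcm4 (-3.13 ± 0.59) was lower and the cyclin gene Ccne1 (2.64 ± 0.36) higher. The DNA replication list had a median log2 fold change of -1.82 and a camera adjusted p of 0.0128 (adjusted p = 0.616 with an estimated correlation). With the length trend removed among genes at a mean of 5 FPKM or more, neither the trophectoderm (median -0.50, adjusted p = 0.508) nor the DNA replication list (-1.01, adjusted p = 0.0669) was called. Of mitotic genes, 8 of 25 fell and none rose (6 adjusted over the list alone; camera adjusted p = 0.170). The inhibitor gene Cdkn1c rose (5.60 ± 0.50). Respiratory chain genes fell in 25 of 27 cases and rose in none (25 adjusted over the list alone), for example Atp5a1 (-3.22 ± 0.44). The respiratory chain list had a median log2 fold change of -1.71 and a camera adjusted p of 4.23e-06 (adjusted p = 0.538 with an estimated correlation). Mitochondrially encoded genes moved the other way. They took 13.4 ± 7.84% of the reads in TGC against 3.19 ± 0.41% at E4.5 (SD, n = 3). Of that list, 5 of 12 tested members rose, 0 fell and 7 did not pass the test (3 and 0 adjusted over the list alone). The mitochondrially encoded list had a median log2 fold change of 1.01 and a camera adjusted p of 0.0496 (adjusted p = 0.636 with an estimated correlation). It lost the call with the length trend removed among all genes with a length (median 1.20, adjusted p = 0.0792), and without E4.5 replicate 1 (median 1.03, adjusted p = 0.0540), E4.5 replicate 2 (median 0.89, adjusted p = 0.0660), E4.75 replicate 1 (median 1.01, adjusted p = 0.0529), E4.75 replicate 2 (median 1.01, adjusted p = 0.0517) or TGC replicate 3 (median 0.43, adjusted p = 0.289). Whether RNA quality has a part in either list was not tested.

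Integrin genes rose in TGC against E4.5 in 6 of 10 cases and fell in none (7 adjusted over the list alone), led by Itgb3 (88.8 ± 50.1 FPKM, 6.13 ± 0.39). The integrin list had a median log2 fold change of 1.29 and a camera adjusted p of 0.0128 (adjusted p = 0.503 with an estimated correlation). Matrix proteases and inhibitors gave 8 higher and 2 lower of 17 (8 and 3 adjusted over the list alone; camera adjusted p = 0.170). The inhibitor gene Tfpi2 (5.53 ± 0.99), the gelatinase gene Mmp9 (4.42 ± 0.62) and the urokinase gene Plau (3.58 ± 0.54) were higher and Serpine2 (-4.43 ± 0.46) lower. The imprinted genes H19 (2181 ± 2352 against 28.5 ± 27.7 FPKM, 6.12 ± 1.21) and Igf2 (4.60 ± 0.69) were higher. Genes of steroid synthesis rose in 4 of 7 cases and fell in 1 (4 and 1 adjusted over the list alone), with the side-chain cleavage gene Cyp11a1 at 4.88 ± 0.61. Camera gave them an adjusted p of 0.0558. It was 0.0496 or less with a pseudocount of 0.1, at the same total, with quantile normalization, with the background subtracted and with the length trend removed. Epithelial junction genes fell in 13 of 24 cases and rose in 2 (13 and 2 adjusted over the list alone), including Cldn4 (-5.94 ± 0.51) and Ocln (-5.67 ± 0.33). Their camera adjusted p was 0.0558, and 0.0496 with a pseudocount of 0.1.

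Some genes used as endothelial markers rose in TGC. Of the 26 genes of the pan-endothelial list only 10 passed the filter, and a gene near 0 in mural trophectoderm passes it only through TGC. Among them, 6 of 10 tested members rose, 0 fell and 4 did not pass the test (6 and 0 adjusted over the list alone). The pan-endothelial list had a median log2 fold change of 1.44 and a camera adjusted p of 0.0241 (adjusted p = 0.503 with an estimated correlation). That call was lost with quantile normalization (median 1.37, adjusted p = 0.0553). It was also lost without TGC replicate 1 (median 0.84, adjusted p = 0.206), TGC replicate 2 (median 0.19, adjusted p = 0.144) or TGC replicate 3 (median 0.67, adjusted p = 0.106). With a TGC library left out, genes seen only in TGC can no longer pass the filter, so these medians may cover fewer members. Cdh5 was at 92.6 ± 92.0 FPKM in TGC and 0.206 ± 0.129 at E4.5 (5.63 ± 0.73, SE), and Pecam1, which is not in the list, at 55.8 ± 56.2 and 1.18 ± 0.837 (4.28 ± 0.62). Esam was at 36.2 ± 28.4 and 0.371 ± 0.0656 (4.45 ± 0.48), and Kdr at 2.19 ± 0.576 and 0.30 ± 0.138 (1.29 ± 0.29). VEGF and angiopoietin genes rose in 4 of 5 cases and fell in none (4 adjusted over the list alone), with the placental growth factor gene Pgf (4.99 ± 0.57) and Vegfa (1.82 ± 0.38) among them. The VEGF and angiopoietin list had a median log2 fold change of 1.82 and a camera adjusted p of 0.0128 (adjusted p = 0.503 with an estimated correlation). Only those 5 of its 14 genes passed the filter, and without TGC replicate 1 or 2 too few passed for a test. The vasodilator peptide gene Adm (6.31 ± 0.91) and the Notch ligand gene Dll4 (3.32 ± 0.54) also rose, and Pdgfa fell (-1.95 ± 0.35). Pdgfa was not called with quantile normalization (-0.67, adjusted p = 0.240) or with the length trend removed among genes at a mean of 5 FPKM or more (-0.81, adjusted p = 0.111).

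Called genes in TGC against E4.5 numbered 6328 of 13368 tested, with 2451 higher and 3877 lower (38.7% higher, median -0.04). With each library at the same total the split was 3442 and 2366 (59.3% higher, median 0.44), and with median-of-ratios size factors 3204 and 3347 (48.9% higher, median 0.17).

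**Figure D2:**
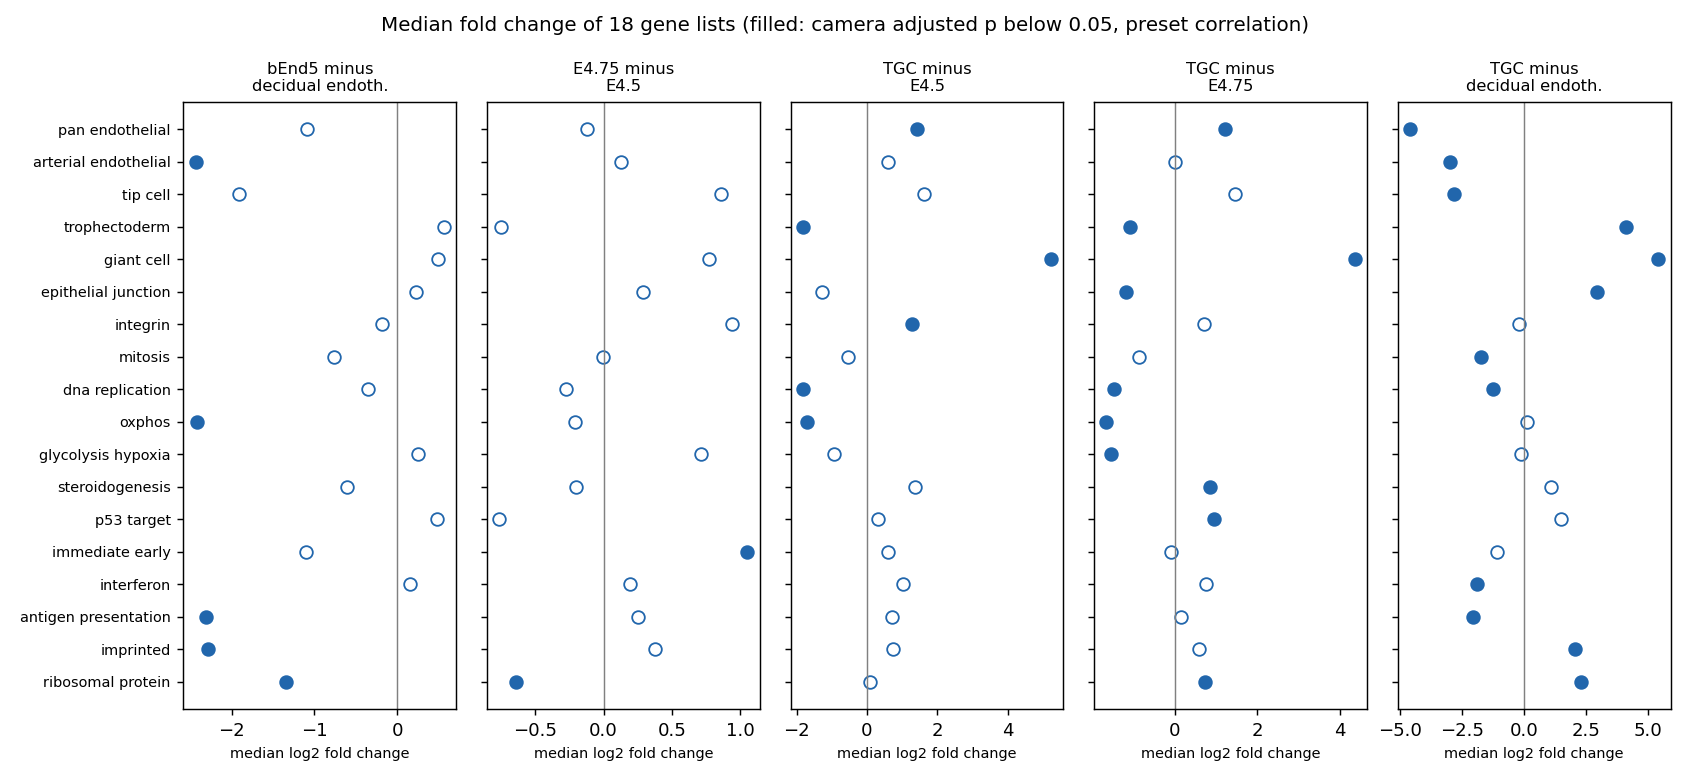
Median log2 fold change of 18 of the 43 gene lists (vertical axis) in the 5 comparisons (panels, each with its own horizontal scale), with filled symbols where camera with its preset correlation gave an adjusted p below 0.05. The giant cell list had its largest medians in the 3 comparisons of TGC, and the respiratory chain (oxphos) list lay below 0 in bEnd5 against decidual endothelium and in TGC against both mural trophectoderm groups.

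Against E4.75 mural trophectoderm, giant cell genes were again higher in TGC. Ceacam15 was at 2145 ± 2303 against 1.61 ± 2.09 FPKM (SD, n = 3), a log2 fold change of 9.23 ± 0.82 (SE). Prl3d1 (8.27 ± 1.03), Prl2c3 (8.26), Ceacam9 (8.19) and Prl7a1 (7.95 ± 1.40) were also among the highest 6. The cathepsin-like gene Ctsll3 (chromosome 13, 60798250 to 60802849) was lower in TGC, at 5.06 ± 1.03 against 10602 ± 3190.3 FPKM (-10.75 ± 0.35). Tspan8 (-10.05 ± 0.49), Dppa1 (-8.74), the glutathione transferase gene Gsta1 (-8.57), Dppa5a (-8.04) and the phospholipase gene Pla2g10 (-7.84) completed the lowest 6. Hand1 was not called between them (2.17 ± 0.87, adjusted p = 0.0731). It was called without TGC replicate 2 (3.42, adjusted p = 6.79e-04) and with the other 3 scalings (2.42 to 3.03), and without TGC replicate 3 it was at 1.36. Pdgfa was lower in TGC (-3.35 ± 0.35).

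Of the pan-endothelial list, 5 of 10 tested members rose, 0 fell and 5 did not pass the test (5 and 0 adjusted over the list alone). The pan-endothelial list had a median log2 fold change of 1.21 and a camera adjusted p of 0.00226 (adjusted p = 0.408 with an estimated correlation). The list kept its call without TGC replicate 1, 2 or 3 (adjusted p = 0.0430, 0.0253 and 0.0152). Its 10 tested members are those of the comparison with E4.5, so genes near 0 in mural trophectoderm entered only through TGC. Such genes can no longer pass the filter with a TGC library left out, so those fits may hold fewer members. In the giant cell list, 17 of 25 tested members rose, 1 fell and 7 did not pass the test (18 and 3 adjusted over the list alone). The giant cell list had a median log2 fold change of 4.36 and a camera adjusted p of 3.09e-08 (adjusted p = 0.531 with an estimated correlation). Of p53 targets, 6 of 16 tested members rose, 0 fell and 10 did not pass the test (7 and 0 adjusted over the list alone). Cdkn1a was at 239.9 ± 238 against 3.80 ± 1.60 FPKM (5.24 ± 0.59). The p53 target list had a median log2 fold change of 0.94 and a camera adjusted p of 7.12e-04 (adjusted p = 0.531 with an estimated correlation), and without TGC replicate 3 the median was 0.49 (adjusted p = 0.00632). Glycolytic and hypoxia genes fell in 10 of 22 cases and rose in none (11 adjusted over the list alone), including the hypoxia target Bnip3 (-5.68 ± 0.54). The glycolytic and hypoxia list had a median log2 fold change of -1.54 and a camera adjusted p of 0.00994 (adjusted p = 0.620 with an estimated correlation). That call was lost with quantile normalization (median -0.76, adjusted p = 0.11) and without TGC replicate 2 (median -1.02, adjusted p = 0.142). It was lost at an unchanged median with the background subtracted (-1.55, adjusted p = 0.0501). In the epithelial junction list, 1 of 24 tested members rose, 14 fell and 9 did not pass the test (1 and 15 adjusted over the list alone). The epithelial junction list had a median log2 fold change of -1.18 and a camera adjusted p of 7.12e-04 (adjusted p = 0.531 with an estimated correlation). Neither this list (median -0.57, adjusted p = 0.112) nor the glycolytic list (-0.91, adjusted p = 0.0721) was called with the length trend removed among genes at a mean of 5 FPKM or more. Steroid synthesis genes rose in 3 of 7 cases and fell in none (3 adjusted over the list alone), led by Cyp11a1 (5.28 ± 0.61). The steroid synthesis list had a median log2 fold change of 0.86 and a camera adjusted p of 0.00629 (adjusted p = 0.531 with an estimated correlation), and without TGC replicate 3 the median was 0.56 (adjusted p = 0.0145). Ribosomal protein genes rose in 10 of 26 cases and fell in 1 (12 and 1 adjusted over the list alone). The ribosomal protein list had a median log2 fold change of 0.73 and a camera adjusted p of 0.00226 (adjusted p = 0.620 with an estimated correlation).

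Of 13368 genes, 4778 were called in TGC against E4.75, with 1786 higher and 2992 lower (37.4% higher, median -0.03). The split was 2408 and 2554 (48.5% higher, median 0.14) with median-of-ratios size factors and 1869 and 2080 (median 0.18) at the same total. Without E4.75 replicate 2 the count was 3181, with 1080 higher, and without E4.75 replicate 1 there were 1171 higher. Strain went with the group here too.

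TGC were set against decidual endothelium to place the signals of the embryonic and maternal sides next to each other. Pdgfa was at 21.1 ± 6.04 FPKM in TGC and 0.376 ± 0.250 in decidual endothelium (SD, n = 3), a log2 fold change of 3.98 ± 0.30 (SE). Pdgfb was at 1.62 ± 1.14 and 27.1 ± 4.68 (-3.50 ± 0.26). Pgf (4.52 ± 0.49) and Vegfa (2.24 ± 0.31) were higher in TGC. The VEGF receptor and co-receptor genes Kdr (-5.26 ± 0.21), Flt1 (-3.60 ± 0.31) and Nrp1 (-5.04 ± 0.26) were higher in the endothelium. Adm was at 256 ± 297 FPKM in TGC (4.76 ± 0.79), and Calcrl (-4.81 ± 0.22) and Ramp2 (-4.64 ± 0.29), whose products form its receptor, were higher in the endothelium. Igf2 was higher in TGC (6.53 ± 0.57), as was Egfr (2.73 ± 0.26). The growth factor gene Areg had 0 reads in the decidual libraries (up to 3 reads per library allowed) and 5.80 ± 7.18 FPKM in TGC. The adjusted p of the genes in this paragraph that carry a fold was at most 1.84e-04.

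**Figure D3:**
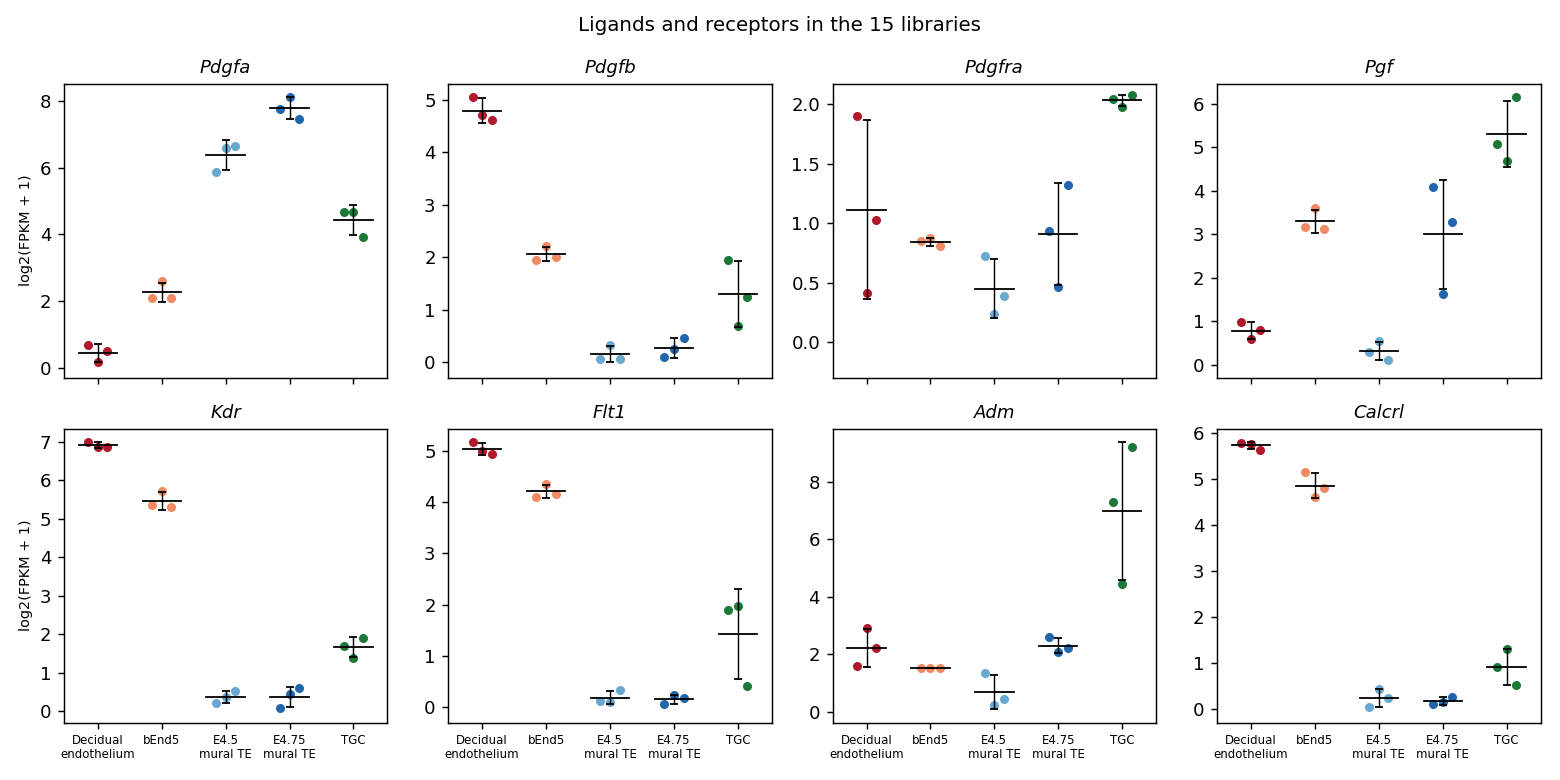
Log2(FPKM + 1) of 8 ligand and receptor genes in each of the 15 libraries (3 points per group), with the group mean (line) and SD (bar, n = 3). Pdgfa, Pgf and Adm were higher in TGC than in decidual endothelium, and Pdgfb, Kdr, Flt1 and Calcrl were higher in decidual endothelium.

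Epithelial and trophoblast genes were higher in TGC, with Krt8 (9.94 ± 0.50), Krt18 (9.22 ± 0.50) and H19 (9.63 ± 1.06) as examples. In the epithelial junction list, 22 of 24 tested members rose, 1 fell and 1 did not pass the test (22 and 1 adjusted over the list alone). The epithelial junction list had a median log2 fold change of 2.94 and a camera adjusted p of 2.25e-10 (adjusted p = 0.0573 with an estimated correlation). In the trophectoderm list, 18 of 20 tested members rose, 1 fell and 1 did not pass the test (18 and 1 adjusted over the list alone). The trophectoderm list had a median log2 fold change of 4.13 and a camera adjusted p of 2.10e-09 (adjusted p = 0.0284 with an estimated correlation). Of the pan-endothelial list, 0 of 26 tested members rose, 23 fell and 3 did not pass the test (0 and 24 adjusted over the list alone). The pan-endothelial list had a median log2 fold change of -4.60 and a camera adjusted p of 6.19e-17 (adjusted p = 0.00610 with an estimated correlation). Cdh5 itself was not called (-1.31 ± 0.63, adjusted p = 0.0914). It was called lower without TGC replicate 3 (-2.16, adjusted p = 0.00248), at the same total (-2.44) and with quantile normalization (-1.61), and was at -0.32 without TGC replicate 2. Among the 6 lowest genes were Rbp7 (-9.48), Sparcl1 (-7.92), Prss29 (-7.88), Ptrf (-7.84) and Ifitm3 (-7.76).

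Interferon-stimulated genes were lower in TGC than in decidual endothelium in 18 of 20 cases and higher in none (19 adjusted over the list alone). The interferon list had a median log2 fold change of -1.90 and a camera adjusted p of 1.39e-09 (adjusted p = 0.00932 with an estimated correlation). Class I antigen presentation genes were lower in 9 of 11 and higher in none (10 adjusted over the list alone), with H2-D1 at -5.36 ± 0.53. The antigen presentation list had a median log2 fold change of -2.08 and a camera adjusted p of 1.34e-05 (adjusted p = 0.00932 with an estimated correlation). Mitotic genes were lower in 21 of 25 and higher in none (22 adjusted over the list alone). The mitotic list had a median log2 fold change of -1.75 and a camera adjusted p of 1.34e-05 (adjusted p = 0.456 with an estimated correlation).

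Lists that can move with RNA quality or preparation differed between these groups too. Mitochondrially encoded genes were higher in TGC in 12 of 12 cases (12 adjusted over the list alone). The mitochondrially encoded list had a median log2 fold change of 3.46 and a camera adjusted p of 4.16e-06 (adjusted p = 0.365 with an estimated correlation). Ribosomal protein genes were higher in 26 of 26 (26 adjusted over the list alone). The ribosomal protein list had a median log2 fold change of 2.30 and a camera adjusted p of 1.10e-10 (adjusted p = 0.264 with an estimated correlation). Among genes at a mean of 5 FPKM or more, the median log2 fold change was 1.44 for 431 genes with up to 1000 bp of exon and -0.55 for 3025 genes with over 4000 bp. Of 16536 genes tested in the fit of the 15 libraries, 8770 were called, with 4543 higher and 4227 lower in TGC (51.8% higher, median 0.14). With each library at the same total the split was 3161 and 7754 (29.0% higher, median -0.73). Quantile normalization also turned the majority (3627 and 4242, 46.1% higher, median 0.04), as did only the 6 compared libraries in the fit (2597 and 3300, 44.0%, median -0.23), the background subtracted (2901 and 4894, 37.2%, median -0.24) and the filter on the mean (3163 and 4000, 44.2%, median -0.14). Median-of-ratios factors gave 4999 and 3763 (57.1%, median 0.25). Slight majorities of lower genes came with a pseudocount of 5 (49.7% higher), with either removal of the length trend (49.7% and 49.3%) and without TGC replicate 2 or 3 (49.7% each). The groups also differed in input to the library preparation (10 ng of purified RNA against 3 µl of lysate), and without the filter 17593 genes were called.

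The changes of E4.75 and of TGC were both measured against the same 3 E4.5 libraries, and their correlation was positive. Across 13368 genes, which are not independent replicates, Pearson's r was 0.590 and the covariance 1.05. Over 100 draws of unchanged groups against shared controls, the mean r was 0.466 (up to 0.945) and the mean covariance 0.0811 (highest 0.472), a difference in covariance of 0.973. Genes called higher in both numbered 565, where independent lists of these sizes share 226 and the draws gave a mean of 0.160. Genes called lower in both numbered 1497, against 539 and 0.150. Genes called higher at E4.75 and lower in TGC numbered 64, and 19 went the other way. The draws held no changed genes, so few calls and a small overlap were set in advance in them. Covariance also grows with the size of the changes, and r lay within the draws. Neither comparison with the draws thus shows that the changes are related. The 3 control libraries could not be split so that each part kept 2, so part of the excess over independent lists may come from the shared controls.

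**Figure D4:**
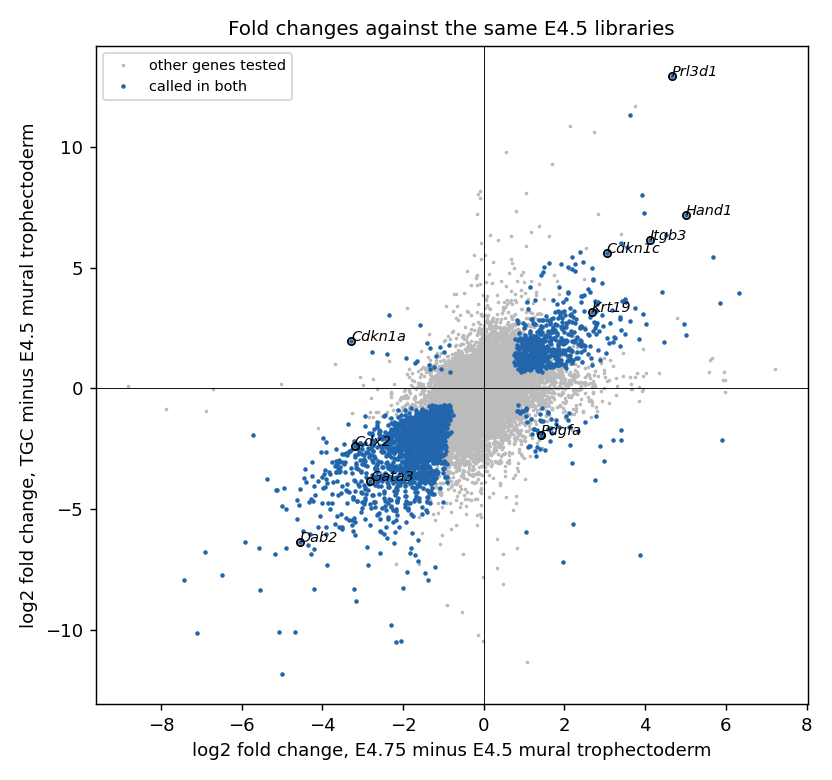
Log2 fold change of each of 13368 tested genes at E4.75 (horizontal axis) and in TGC (vertical axis), both against the same E4.5 mural trophectoderm libraries, with genes called in both comparisons in blue and other genes in gray. Hand1, Prl3d1, Cdkn1c and Itgb3 were higher in both, Dab2 and Gata3 lower in both, Pdgfa was higher at E4.75 and lower in TGC, and Cdkn1a lay below 0 at E4.75 and above 0 in TGC; Krt19 is also labelled.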

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

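The comparison with endothelial sources was chosen after its result had been seen, and the subtraction of the background, the removal of the length trend and the scalings of the covariance were added after the data had been seen.

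Olfactory receptor genes, which lie outside every comparison and are silent in most tissues, averaged 0.388 FPKM in bEnd5 and 0.544 in TGC, 0.191 at E4.5 and 0.138 at E4.75, all above the 0.00451 of decidual endothelium. The 3 TGC libraries stood at 0.270, 1.06 and 0.301 (SD 0.448), so replicate 2 carried the TGC mean. Further measurements were made on this signal. The 81 genes of chromosome Y other than Ddx3y, Eif2s3y, Kdm5d and Uty averaged 0.0356 ± 0.00410 (SD, n = 3) of the olfactory mean in bEnd5. This ratio was 0.440 ± 0.226 in decidual endothelium, 2.91 ± 0.997 at E4.5, 2.26 ± 0.802 at E4.75 and 2.90 ± 0.735 in TGC. In bEnd5, Spearman's rho between reads and exon length was 0.160 across 1235 olfactory genes. Their squared deviation from a Poisson model was 4.56 times the Poisson variance at the median.

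Endothelial genes were called higher in TGC than in E4.5 mural trophectoderm (6 of the 10 members of a list of 26 that passed the filter, and Pecam1), with Cdh5 at 69.8, 14.2 and 194 FPKM in the 3 TGC libraries. Endothelial cells or their RNA would bring their abundant transcripts along. The levels of 33 genes of decidual endothelium and 8 of bEnd5 were set relative to what the Cdh5 level implied. These ratios had medians of at most 0.0672, which argues against these 2 sources for the Cdh5 level. The implied shares of decidual endothelium were 47.7%, 9.70% and 132%. The ratios rest on Cdh5 alone, so they do not decide on these 2 sources for the other called genes, where both stay open. With the olfactory mean subtracted, 5 of the 7 called genes stayed called, which argues against background at that level for these 5. The others, Kdr and Plvap, fell below the filter, so for them background stays open. The 81 genes of chromosome Y measured above averaged 0.948, 3.29 and 0.626 FPKM in TGC replicates 1, 2 and 3. These lie above the olfactory means, and a background of that size was not tested. Endothelial cells of another kind stay open, as does the spread between the 3 TGC libraries. Without TGC replicate 1, 2 or 3 the list lost its call against E4.5 (median 0.84, 0.19 or 0.67). It kept the one against E4.75 (median 1.06, 0.87 or 1.28, adjusted p of at most 0.0430). Genes seen only in TGC can no longer pass the filter in those fits, so they do not show what each library carried. As a hypothesis, giant cells in culture may express some endothelial adhesion genes themselves.

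Genes of several lists were lower in bEnd5 than in decidual endothelium, and short transcripts were lower there as a class. With the length trend removed among genes at a mean of 5 FPKM or more, the ribosomal protein median went from -1.34 to 0.16, so that the trend could account for that list. The respiratory chain median shrank from -2.41 to -1.35 and stayed called at the preset correlation (camera adjusted p = 0.00295; without the removal, adjusted p = 0.756 with an estimated correlation), which argues against the trend as the whole cause there. For the antigen presentation and arterial lists, of which 8 of 11 and 11 of 14 members reached that level, the version with all lengths was used instead, a choice made after these values were seen; the medians went from -2.30 to -1.72 (adjusted p = 0.0123) and from -2.43 to -2.24 (adjusted p = 2.25e-04; without the removal, adjusted p = 0.724 and 0.724 with an estimated correlation), which again argues against the trend as the whole cause. Culture against tissue, the brain origin of the line and its endothelioma state go together here and cannot be told apart. They stay open as biological differences, untested, as does the sort of the decidual cells.

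E4.75 and E4.5 mural trophectoderm differed in stage and in strain. TGC have the strain of E4.5. The prediction for a strain difference alone was fold changes of E4.75 and TGC that covary no more than in unchanged groups with shared controls. The covariance was 1.05 against a highest simulated value of 0.472 (1.85 against 1.38 with a pseudocount of 0.1, 0.552 against 0.188 with 5, 1.04 against 0.510 at the same total, 0.813 against 0.364 with quantile normalization and 1.01 against 0.426 with median-of-ratios factors). Pearson's r, 0.590, lay within the draws (mean 0.466, up to 0.945). The draws held no changed genes. They do not show how far a strain difference and a culture difference from the same E4.5 levels would covary, so the covariance does not decide on strain. For 394 genes called higher and 175 called lower at E4.75 against both B6C3F1 groups, with TGC and E4.5 not called apart, strain and stage stay open together. Anything that set the 3 E4.5 libraries apart in handling would also raise the covariance and stays open.

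With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 8077 genes in bEnd5 against decidual endothelium (highest other split 0), 3090 in E4.75 against E4.5 (0), 6328 in TGC against E4.5 (0), 4778 in TGC against E4.75 (0) and 8770 in TGC against decidual endothelium (1). In each case 1 split, the real one, gave as many.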

How the results depend on the processing

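Voom on the recovered reads, the subtraction of the background and the removal of the length trend were chosen after the data were seen, as were the scalings for the correlation of fold changes; the other alternatives were planned. Total counts of called genes kept within 1.5 times their main value except as follows, with left-out libraries given as ranges. Without the filter, 22712 genes were called in bEnd5 against decidual endothelium, 1931 in E4.75 against E4.5 and 17593 in TGC against decidual endothelium, where 2 to 3 times as many genes were tested. With the length trend removed among genes at a mean of 5 FPKM or more, which tests fewer genes, the counts were 4259 in bEnd5, 3649 in TGC against E4.5, 2920 in TGC against E4.75 and 3742 in TGC against decidual endothelium. Array weights gave 6598 for E4.75 against E4.5, and the cause was not tested. Leaving out 1 library gave 5988 to 8022 genes in bEnd5 against decidual endothelium, 1723 to 3881 in E4.75 against E4.5, 5139 to 6196 in TGC against E4.5, 3181 to 4654 in TGC against E4.75 and 7247 to 8783 in TGC against decidual endothelium; why single libraries mattered was not tested beyond the smaller number of libraries. Counts in 1 direction moved further in some fits whose totals did not. With all 15 libraries in 1 fit, 1864 genes were higher at E4.75 (1233 in the report), 3854 in TGC against E4.5 (2451) and 3178 in TGC against E4.75 (1786), and with array weights 2965 in the last. TGC against decidual endothelium had 2597 higher with only its 6 libraries and 2901 with the background subtracted (4543). At the same total, 863 genes were lower at E4.75 (1857), 2366 in TGC against E4.5 (3877) and 7754 in TGC against decidual endothelium (4227). Where a group kept 2 libraries, they were taken to vary like the other groups of the fit.

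Over the 5 comparisons camera called 48 list shifts, 37 to 55 under the other alternatives and 7 with an estimated correlation. All 7 were in TGC against decidual endothelium. They included the tip cell list, with 13 of 16 members lower and 2 higher (adjusted p = 0.00985). The VEGF and angiopoietin list was another, with 8 of 12 lower and 2 higher (adjusted p = 0.0426). In TGC against E4.5 the estimated correlation was 0.523 for the giant cell list and 0.00291 for the pan-endothelial list, beside the preset 0.01. Both lists lost their call, and the cause of the drop was not tested. Of the 50 list results in the text, 433 of 495 values under alternatives other than left-out libraries kept their call, 43 lost the call, 18 gained one and 1 turned around: the median of ribosomal protein genes in bEnd5 was 0.16 with the length trend removed among genes at a mean of 5 FPKM or more, after -1.34. Of the 165 fold changes of genes in the text, 3864 of 3890 values, left-out libraries included, kept their call, 6 lost the call, 20 gained one and 0 turned around among called genes. Fits in which a gene no longer passed the filter gave no value for it and are not counted as lost calls. Many of these genes were named for large changes in the same data, which favours stable calls. Cdh5 and Pecam1 in bEnd5, which were not called, changed sign around 0 with single libraries left out. With each library left out in turn, the 48 called list shifts kept their call in 515 of 547 values and lost it in 32; the VEGF and angiopoietin list in TGC against E4.5 could not be tested without TGC replicate 1 or 2, and lists without a call were not followed. Pearson's r of the E4.75 and TGC changes, 0.590, was 0.525 to 0.618 over its alternatives and left-out libraries (0.532 to 0.618 over the left-out libraries). Its covariance, 1.05, was 1.85 with a pseudocount of 0.1 and 0.552 with 5.

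With the replicate number as a block (replicate block), 7596 genes were called in bEnd5 against decidual endothelium, 3057 in E4.75 against E4.5, 6516 in TGC against E4.5, 4995 in TGC against E4.75 and 8719 in TGC against decidual endothelium, and camera called 50 list shifts. Deviations of libraries with the same number correlated at -0.09, -0.21 and -0.01 in the endothelial comparison, at 0.28, 0.08 and 0.11 between E4.75 and E4.5, and at 0.24, 0.09 and 0.02 between TGC and E4.5. They lay at 0.17, 0.15 and -0.22 between TGC and E4.75 and at -0.03, -0.04 and 0.03 between TGC and decidual endothelium. The highest correlation with another number was 0.19, 0.11 and 0.04 in the endothelial comparison. Between TGC and decidual endothelium it was 0.032, 0.065 and 0.035, so the numbers did not pair the libraries of these 2 comparisons. It was -0.11, 0.18 and 0.06 between E4.75 and E4.5, -0.12, 0.11 and -0.0036 between TGC and E4.5, and -0.09, 0.31 and 0.24 between TGC and E4.75. A partial pairing of the trophoblast libraries stays open. The block made camera call the giant cell and integrin lists at E4.75 (adjusted p = 0.0323 and 0.0342) and limma call Hand1 in TGC against E4.75 (0.0469).

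Depth can limit what is seen of genes at low levels, which was not tested. The shallowest library, of TGC, held 4.32 M reads against 22.5 M in the deepest at E4.75. With 3 libraries per group, simulated 2-fold changes were recovered in 3% of genes for E4.75 against E4.5. In bEnd5 against decidual endothelium the share was 37%. A gene that was not called is thus not shown to be unchanged. The simulated changes were in genes at a mean of 10 FPKM or more, so these shares do not bear on low levels. The deeper pair of groups had the lower share, so they do not measure depth either.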

Other observations

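In bEnd5 against decidual endothelium, single members were called in the next 3 lists, none of which camera called. Of angiogenic tip cell genes, 2 of 16 tested members rose, 11 fell and 3 did not pass the test (2 and 11 adjusted over the list alone), with Igfbp3 (-5.80 ± 0.15, SE) and Esm1 (-5.08 ± 0.15) lower; camera gave an adjusted p of 0.134. Of genes of cholesterol synthesis and uptake, 1 of 19 tested members rose, 13 fell and 5 did not pass the test (1 and 13 adjusted over the list alone), with Fdps at -2.44 ± 0.17 (camera adjusted p = 0.134). Glycolytic and hypoxia genes rose in 10 of 22 cases and fell in 4 (10 and 4 adjusted over the list alone), with the oxygen sensor gene Egln3 at 4.66 ± 0.18; camera called the list only with quantile normalization (median 0.93, adjusted p = 0.0278). The venous gene Lrg1 was lower (-6.14 ± 0.35) and the p53 target Eda2r higher (3.92 ± 0.15). At E4.75, the leukocyte marker gene Cd52 (4.47 ± 0.56) and the lipoprotein gene Apoa1 (5.59 ± 0.81), a marker of endoderm, were higher than at E4.5, and Efna1 (-3.97 ± 0.79) was lower.

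In TGC against E4.75 mural trophectoderm, respiratory chain genes fell in 23 of 27 cases and rose in none (24 adjusted over the list alone), with Ndufs1 (-3.35 ± 0.32, SE) and Cycs (-3.19 ± 0.35) as examples and a median log2 fold change -1.66, camera adjusted p = 1.14e-07, and adjusted p = 0.531 with an estimated correlation. DNA replication genes fell in 16 of 29 cases and rose in none (23 and 1 adjusted over the list alone), with a median log2 fold change -1.47, camera adjusted p = 7.12e-04, and adjusted p = 0.620 with an estimated correlation. That call was lost with the length trend removed among genes at a mean of 5 FPKM or more (median -0.81, adjusted p = 0.0533). Against E4.5, TGC had higher Bst2 (3.94 ± 0.72), an interferon-stimulated gene, and Thbd (3.90 ± 0.63), and lower Bnip3 (-7.28 ± 0.54) and the imprinted genes Snrpn (-4.28 ± 0.61) and Slc38a4 (-4.53 ± 0.40). Against decidual endothelium, basement membrane genes fell in 16 of 20 cases and rose in 4 (16 and 4 adjusted over the list alone), with Col18a1 (-4.37 ± 0.29) and Nid2 (-4.20 ± 0.31) lower and Lama1 (2.67 ± 0.35) higher and a median log2 fold change -1.86, camera adjusted p = 5.15e-04, and adjusted p = 0.264 with an estimated correlation. Arterial genes fell in 13 of 14 cases there and rose in none (14 adjusted over the list alone), with a median log2 fold change -2.99, camera adjusted p = 1.57e-08, and adjusted p = 0.00985 with an estimated correlation. The imprinted gene Phlda2 was higher in TGC than in decidual endothelium (7.17 ± 0.73) and Mest lower (-5.91 ± 0.33).

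Reads of Prl3d1, a giant cell gene, were present in bEnd5, at 10.3 ± 8.57 FPKM (SD, n = 3), and in decidual endothelium, at 3.74 ± 5.07. The TGC libraries held 15681 ± 18312. The source of the reads in the endothelial groups was not tested.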
